A study of Homo sapiens with 16 samples.

How the data were processed

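The samples were cells labelled Huh7. RNA-seq of polyadenylated RNA covered sorafenib against DMSO (3 and 3 libraries) and MT1G overexpression against empty vector (3 and 3), and ATAC-seq covered sorafenib (replicates 3 and 4 by their titles) against DMSO (replicates 1 and 2). Groups were taken from the sample titles. The columns of each RNA table, 3 for treatment and 3 for control, were assumed to follow the replicate numbers of the titles.

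Per the submitters' processing notes, the software was cutadapt, HISAT2, featureCounts 1.6.1, DESeq2, Bowtie2 2.4.1, Picard, SAMtools and MACS2 2.2.7.1 with the hg38 genome, and the notes gave them no role or order. The RNA signal values, normalized read counts for 59609 genes, were made by the authors from reads counted per gene and divided by a size factor per library. The values were checked for this: each column, multiplied by its factor, gave whole numbers within a tolerance of 0.001 for 100% of genes. The log2 fold changes and their standard errors in the deposited comparison tables came from the authors' comparison of the groups of 3 libraries. The test score in those tables, fold change over standard error, and the p-value and adjusted p-value per gene were also made by the authors. In the deposited peak lists the score was 10 times the -log10 q of a peak, and the ratio was the fold enrichment at the summit over local background, both written by the authors' peak caller. The deposited lists also held the -log10 p and -log10 q of each peak, and their lowest values were those of lists made by the authors at a q of 0.05.

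Genes were tested with limma 3.58.1 in R 4.3.3 (moderated linear model with trend and robust variance, two-sided) on the log2 of the normalized read count plus 1, for genes with a mean of at least 10 over the 6 libraries. This was the choice written for normalized values before the data were examined, as were the gene lists, the naming rule and most of the other settings tried. Adjusted p-values followed Benjamini and Hochberg with a threshold of 0.05. Each comparison used its own 6 libraries. Reads per library, recovered with the size factors, ran from 16549330 to 26781600. A group at 0 reads in all 3 libraries was set to a floor of 3 reads over the group to bound a fold, and groups with 1 to 3 reads got a 95% counting interval of the ratio.

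There were 29 fixed lists with 616 genes, and the 26 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. Medians of each list were also compared with 10000 random lists matched in 50 bins of mean expression, by the range from percentile 2.5 to percentile 97.5. Further lists were written after the first results and are given with the other observations. Named genes were DNMT1, MT1G, KLF4 and CA9, the 6 largest rises and falls past the threshold with a mean of at least 100 and no overlap between groups, and up to 3 members with the smallest p, among those past the threshold in the direction of most such members, of each list that passed camera or had at least 3 members past the threshold. The rule also took the most abundant member of each cell type list, and not every gene it picked is printed. Members that went against their list were named after their values were seen. Other genes named outside this rule are said to be so.

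The overlap of both RNA comparisons was tested with Fisher's exact test on genes tested in both. ATAC-seq peaks on chromosomes 1 to 22, X and Y were merged when they shared at least 1 bp, and a merged region was called gained when both sorafenib libraries and neither DMSO library had a peak in it, and lost in the reverse case. The gene table gave no strand, so the planned test at transcription starts was not run. Regions within 2 kb of the gene span were used in its place, and median log2 changes were compared with 100000 permutations of gene labels, in 10 classes of span length. Of 14915 tested genes 13541 (90.8%) had a place in the gene table. The compared groups were genes with a lost and no gained region, with a gained and no lost region, and with neither and a region open in all 4 libraries. The 1211 genes with both kinds and the 661 with neither kind and no region in all 4 libraries were left out.

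Other settings chosen beforehand were TMM factors, no filter on low values, pseudocounts of 0.5 and 5, DESeq2 1.42.0 on recovered reads, a replicate block, leaving out each library in turn, a minimum absolute log2 change of 1, an estimated correlation, a mean of at least 100 in both comparisons, peaks with a -log10 q of at least 5, an equal number of top peaks, and overlap of most of the shorter peak (a fraction of at least 0.5). Added after the data were seen were edgeR 4.0.16 on recovered reads, gene span windows (2 kb, 500 bp and 10 kb, and no length classes), matched random lists and the metallothionein list without MT1G. The pipeline was tested on simulated data: with 200 genes changed by 1.5-fold, 2-fold or 4-fold, it recovered 65.7%, 82.1% and 97% of these changes in the sorafenib libraries and 68.7%, 80.6% and 98.5% in the MT1G libraries. In the data 70.3% and 22.8% of tested genes were called. The adjusted threshold depends on that share, so these rates are not the sensitivity of the reported tests. Drawing used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. No GC content was used because no genome sequence was at hand, and no test of reads shared between metallothionein genes could be made without the reads.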

Results

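Messenger RNA selected by its poly(A) tail was sequenced in 12 libraries, and open chromatin was mapped by ATAC-seq, which marks accessible DNA by transposase insertion, in 4 libraries. All samples were labelled Huh7, a human hepatocellular carcinoma cell line. In the first RNA experiment 3 samples received sorafenib, a kinase inhibitor used against liver cancer, and 3 received its solvent DMSO. In the second, 3 samples overexpressed MT1G, a metallothionein (a small cysteine-rich protein that binds zinc and copper), and 3 carried an empty vector. The ATAC-seq libraries came from 2 samples with sorafenib and 2 with DMSO. The labels gave neither a dose nor a treatment time. The sorafenib libraries held 21082356, 19542500 and 16549330 reads counted in genes, and the DMSO libraries 18243722, 21074785 and 19533077. The MT1G libraries held 20554100, 16844722 and 26781600, and the vector libraries 18641130, 23324749 and 18116136. Nothing in the labels said that replicates were separate cultures, so a p-value measures the spread between these samples only. Intervals and floors from read counts cover counting error only.

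With sorafenib, transcripts of the metallothionein MT1G rose from 0 reads in all 3 DMSO libraries to 180 ± 19.8 normalized read counts (SD, n = 3). That was at least 170-fold higher, counted against a floor of 3 reads over the 3 control libraries. KLF4, a zinc finger transcription factor, rose 7.98-fold, and CA9, a membrane carbonic anhydrase induced by low oxygen, fell to 1.75% of its control level. Histone, metallothionein and NF-kB inflammatory transcripts rose by medians of 4.14, 6.13 and 3.41 on the log2 scale, and sterol synthesis and NRF2 antioxidant transcripts fell by medians of 0.648 and 0.617. These list calls did not hold with an estimated correlation (adjusted p = 0.104, 0.0786, 0.0786, 0.149 and 0.117 in that order). That setting has few degrees of freedom with 6 libraries, so a lost call does not show that a list was unchanged. Of 14915 genes tested with limma, 5137 were higher and 5347 lower with sorafenib at an adjusted p threshold of 0.05.

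The series title names DNMT1, MT1G, KLF4 and CA9 as an axis in the response to sorafenib. KLF4 (chromosome 9, 107484852 to 107489769 on hg38) stood at 652 ± 37.6 normalized read counts with sorafenib and 80.8 ± 4.77 with DMSO (n = 3 each; log2 change 3.00, SE 0.10, adjusted p = 4.87e-13). CA9 (chromosome 9, 35673928 to 35681159) stood at 4.80 ± 4.62 and 282 ± 129 (log2 change -5.84, SE 0.66, adjusted p = 0.000294). The log2 change of CA9 was -6.46 without sorafenib replicate 2 and -4.88 with a pseudocount of 5, the ends of its range over 12 alternatives. MT1G (chromosome 16, 56666730 to 56668065) passed the same test with an adjusted p of 1.4e-11. DNMT1, the maintenance DNA methyltransferase (chromosome 19, 10133346 to 10194953), stood at 6520 ± 157 with sorafenib and 6802 ± 175 with DMSO. Its log2 change of -0.06 had a 95% interval from -0.18 to 0.05 and did not pass the test (adjusted p = 0.328). The deposited comparison table of the authors gave log2 changes of -0.06 for DNMT1, 9.86 for MT1G, 3.01 for KLF4 and -5.86 for CA9. Its value for MT1G rests on a control group at 0.

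**Figure D1:**
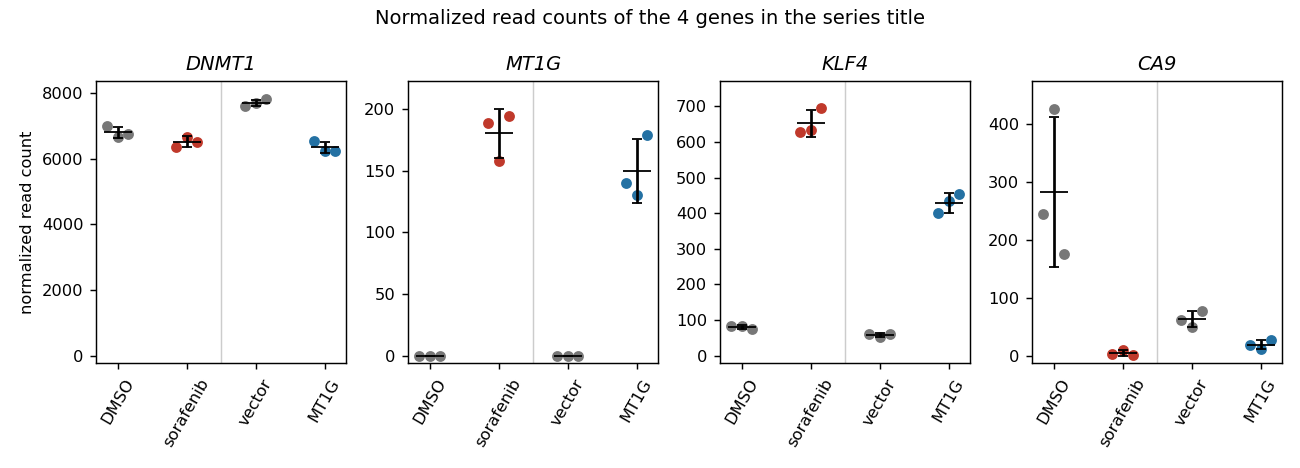
Normalized read counts (vertical axis) of DNMT1, MT1G, KLF4 and CA9 in each RNA library, with the mean and SD of 3 libraries per group as a bar. MT1G had 0 reads in both control groups, KLF4 was higher and CA9 lower in both treated groups, and DNMT1 passed the test with MT1G overexpression (a call lost without vector replicate 2 or 3, adjusted p = 0.0618 and 0.0668) and not with sorafenib, a difference that was not tested.

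The 6 largest rises among abundant genes with separate groups were in MT1B, NEURL3, SLC30A2, NGFR, CXCL8 and RNVU1-34. SLC30A2, a zinc exporter, and NGFR, a nerve growth factor receptor, had 0 reads with DMSO and were at least 252-fold and at least 245-fold higher with sorafenib. MT1B had 3 reads over the DMSO libraries, for a ratio of 758 with a counting interval from 259 to 3675. NEURL3, a ubiquitin ligase gene, had 2 DMSO reads and a ratio of 658 (interval from 182 to 5435). RNVU1-34, a U1 small nuclear RNA variant listed as a pseudogene, had 2 DMSO reads and a ratio of 343 (interval from 94.6 to 2836). The neutrophil chemokine CXCL8 rose from 5.35 ± 1.45 to 1273 ± 54.3 normalized read counts (log2 change 7.67). The 6 largest falls were in CA9, in 4 mitochondrial transfer RNAs and in the cytolinker EPPK1. Log2 changes were -4.83 for MT-TY, -4.31 for MT-TC, -3.85 for MT-TL1, -3.83 for MT-TN and -3.76 for EPPK1.

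Among the gene lists fixed beforehand, 7 were higher with sorafenib by camera, the set test of limma. All 6 tested metallothioneins rose (median 6.13, also with MT1G at its bound, camera adjusted p = 3.03e-06, and adjusted p = 0.0786 with an estimated correlation). MT2A rose to 59860 ± 2960, MT1E to 36010 ± 304 and MT1X to 5546 ± 660 normalized read counts, from 5878 ± 704, 2142 ± 213 and 51.2 ± 8.63. Metallothionein genes have near-identical sequences, and how reads matching several of them were counted was not stated. All 17 tested replication-dependent histone genes rose (median 4.14, camera adjusted p = 5.19e-10, and adjusted p = 0.104 with an estimated correlation), among them H2AC6 with a log2 change of 5.31, H3C10 with 5.36 and H2BC9 with 4.73. These transcripts normally lack a poly(A) tail, and the libraries were made from poly(A) RNA. Of 16 NF-kB inflammatory genes 15 rose and none fell (median 3.41, camera adjusted p = 5.19e-10, and adjusted p = 0.0786 with an estimated correlation). CXCL3 rose by 6.18 and TNFAIP3, a brake on NF-kB signalling, by 4.59 on the log2 scale.

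Genes read as output of the ERK pathway rose in 14 of 19 cases and fell in 3 (median 1.28, camera adjusted p = 3.8e-05, and adjusted p = 0.0786 with an estimated correlation). The early response factors EGR1, FOS and FOSL1 changed by 5.69, 4.10 and 2.39 on the log2 scale. Of 33 ATF4 amino acid response genes 17 rose and 8 fell (median 0.229, camera adjusted p = 0.00566, and adjusted p = 0.197 with an estimated correlation). ATF3 rose by 4.17, PPP1R15A by 3.84 and SESN2 by 2.77, while DDIT4 changed by -1.68. Of 20 p53 target genes 12 rose and 4 fell (median 0.702, camera adjusted p = 0.00665, and adjusted p = 0.197 with an estimated correlation), with AEN at 1.38 and the death receptor TNFRSF10B at 1.09. Of 18 KLF and SP factors 8 rose and 3 fell (median 0.292, camera adjusted p = 0.0159, and adjusted p = 0.198 with an estimated correlation). KLF6 rose by 2.83 and KLF10 by 1.94, while SP1 changed by -1.10.

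The lower lists numbered 8. Sterol biosynthesis genes fell in 24 of 25 cases (camera adjusted p = 1.95e-08, and adjusted p = 0.149 with an estimated correlation), with log2 changes of -2.45 for SQLE and -1.46 for INSIG1. Fatty acid synthesis genes fell in 11 of 14 cases and rose in 1 (median -0.502, camera adjusted p = 0.00102, and adjusted p = 0.104 with an estimated correlation), with ACLY at -1.27. NRF2 antioxidant genes fell in 23 of 25 cases and rose in 1 (camera adjusted p = 3.34e-07, and adjusted p = 0.117 with an estimated correlation), and HMOX1, which degrades heme, changed by -2.44. All 19 glycolysis genes fell (camera adjusted p = 3.03e-06, and adjusted p = 0.149 with an estimated correlation), including the lactate exporter SLC16A3 at -1.74 and LDHA at -1.17. Hypoxia-inducible genes fell in 25 of 32 cases and rose in 4 (median -0.598, camera adjusted p = 0.000389, and adjusted p = 0.282 with an estimated correlation), with DDIT4 at -1.68 and CA12 at -1.58, against BHLHE40 at 1.27 and ADM at 1.25. The hypoxia list shares LDHA, GAPDH, ENO1 and other members with the glycolysis list, and CA9 and CA12 with the carbonic anhydrases. The falls of these lists are therefore partly those of the same genes. All 13 mitochondrially encoded protein genes fell (median -0.686, camera adjusted p = 1.24e-05, and adjusted p = 0.197 with an estimated correlation), MT-CO2 by 1.88 and MT-CO1 by 1.26. Nuclear respiratory chain genes fell in 29 of 35 cases and rose in 1 (median -0.457, camera adjusted p = 1.06e-05, and adjusted p = 0.342 with an estimated correlation), SDHA by 0.98. The share of counts from mitochondrial genes was 3.50 ± 0.13% with sorafenib and 4.88 ± 0.18% with DMSO. Of 8 hepatocyte genes with enough reads 7 fell (median -0.965, camera adjusted p = 0.00432, and adjusted p = 0.164 with an estimated correlation), including the urea cycle enzymes CPS1 at -1.38 and ASS1 at -0.90. The other 26 of the 34 list members were under the minimum mean, so this result covers a small part of the list.

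**Figure D2:**
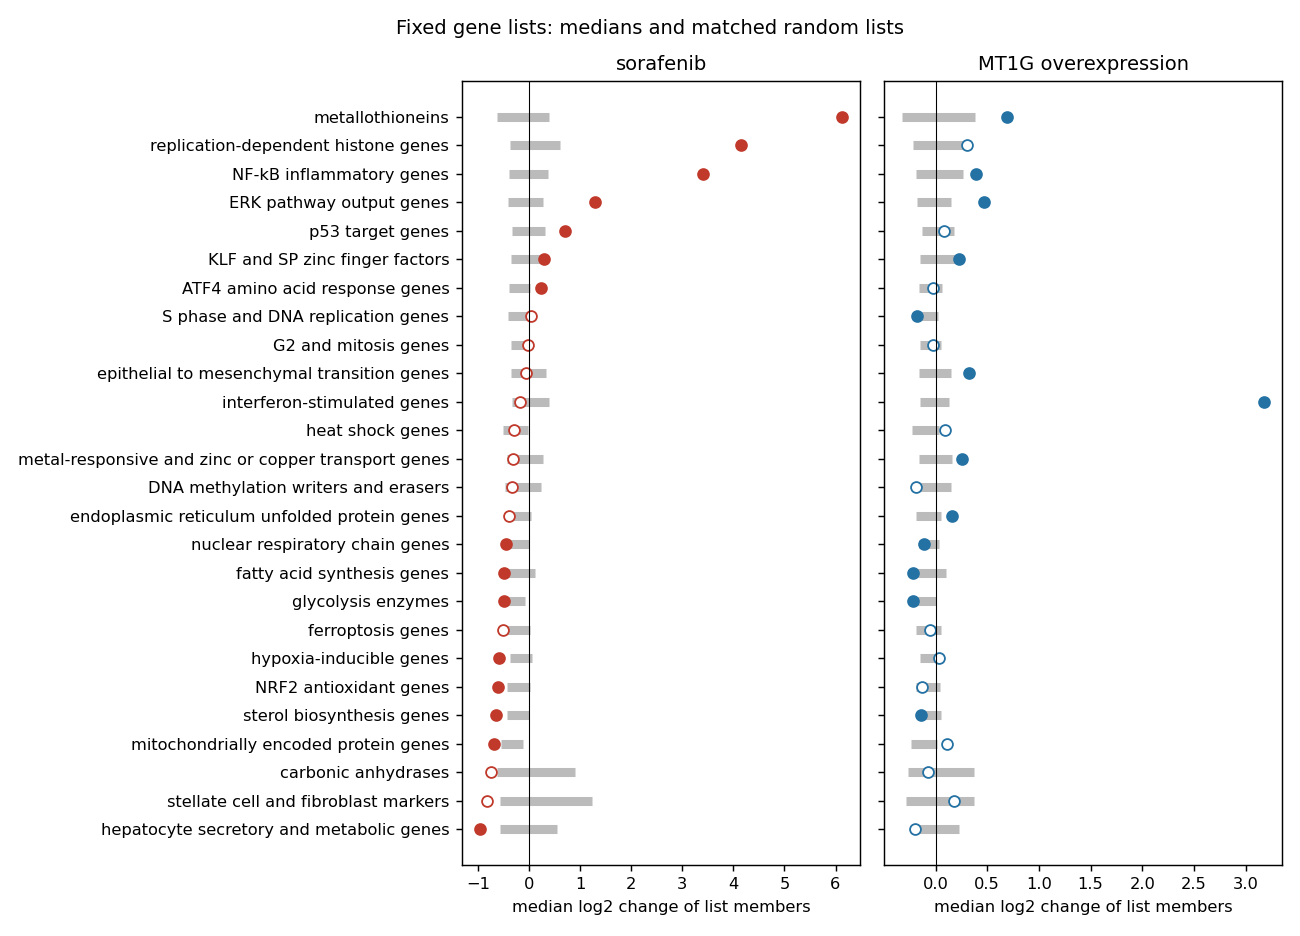
Median log2 change of the members of each fixed gene list (horizontal axis) with sorafenib and with MT1G overexpression. Filled points passed camera at an adjusted p of 0.05, open points did not, and grey bars span 95% of 10000 random gene lists of the same size and mean expression.

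In lists that went both ways, members against the majority were named after their values were seen. Of 35 S phase genes 12 rose, led by E2F1 at 0.76, and 12 fell, with UHRF1 at -0.78 (median 0.0311, camera adjusted p = 0.864). Of 35 G2 and mitosis genes 9 rose and 11 fell, with TOP2A at -2.10 and CDC20 at 0.75 (median -0.0258, camera adjusted p = 0.468). Of 21 interferon-stimulated genes 3 rose and 9 fell, with OAS1 at -1.33 and IFIH1 at 0.91 (median -0.173, camera adjusted p = 0.184). Ferroptosis genes went both ways, 6 up and 14 down of 20, with ACSL4 at -1.18, SAT1 at 2.36 and PTGS2 at 2.24 (camera adjusted p = 0.0762). Unfolded protein genes gave 4 up and 13 down of 21, with PDIA6 at -0.99 and HERPUD1 at 1.26 (camera adjusted p = 0.0709). DNA methylation writers and erasers gave 3 up and 7 down of 13, with IDH1 at -1.29 and UHRF2 at 0.60 (camera adjusted p = 0.116). Metal transport genes gave 2 up and 9 down of 14 (camera adjusted p = 0.118): the zinc exporter SLC30A1 rose from 2479 ± 144 to 21820 ± 716 (log2 change 3.14), and the metal sensor MTF1 by 0.87, while the zinc importer SLC39A10 was at -1.06. Carbonic anhydrases had 4 of 6 lower, with CA12 at -1.58 (camera adjusted p = 0.0631, and 0.0465 without sorafenib replicate 2, in a range up to 0.0758 over the leave-one-out fits). Heat shock genes gave 5 up and 8 down of 14, with HSPE1 at -0.99 and BAG3 at 0.49 (camera adjusted p = 0.279). Mesenchymal transition genes gave 6 up and 9 down of 19, with SNAI2 at 3.07, CCN1 at 1.55 and CCN2 at 2.05 against ITGA5 at -1.36 (camera adjusted p = 0.955), and their median of -0.0666 differed in sign from their mean of 0.215 and from the test. Of 6 stellate cell markers 1 rose and 3 fell, and the most abundant, LUM, stood at 447 ± 39.1 with sorafenib and 1780 ± 88.1 with DMSO (camera adjusted p = 0.188). Acute phase, leukocyte and endothelial lists had 3, 2 and 2 members above the minimum and were not tested, and the endothelial marker CDH5 stood at 50.7 ± 3.37 with DMSO. Adjusted over the list alone, the counts up and down were the same except for p53 targets at 13 and 4, respiratory chain genes at 1 and 31, hepatocyte genes at 1 and 7, and metal transport genes at 3 and 9.

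With a correlation estimated for each list, 0 of the 26 lists passed camera, and at an unadjusted p under 0.05 there were 4 higher and 4 lower. The lowest unadjusted camera p was 0.00328. This setting takes its degrees of freedom from the 6 libraries and not from the number of genes. How much of the loss came from that, and how much from correlation between genes, was not tested. The fry test of limma, which asks whether the genes of a list move one way on balance, passed 24 lists, and its mixed form, which asks for change in either direction, passed 26. Neither form compares a list with the other genes. With 70.3% of tested genes called, passing fry therefore does not set a list apart. The mesenchymal transition list passed fry (adjusted p = 7.58e-05) and not camera (adjusted p = 0.955).

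Over all genes, 10881 of 14915 had groups that did not overlap, where chance gives 10%. Abundant genes fell more often than scarce ones: the 10% of genes with the highest mean had a median log2 change of -0.316 and the 10% with the lowest mean 0.516. The KLF and SP median of 0.292 and the glycolysis median of -0.504 lay inside the 95% range of random lists matched on mean expression, from -0.364 to 0.339 and from -0.519 to -0.0773.

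With MT1G overexpression, interferon-stimulated transcripts had the highest median change of the 26 fixed lists tested: 19 of 25 were higher and none lower, with a median log2 change of 3.18. OASL went from 181 ± 15.7 to 12960 ± 829 normalized read counts, and the ubiquitin-like modifier ISG15 from 742 ± 39.6 to 12930 ± 688 (n = 3 each). KLF4 rose 7.25-fold and CA9 fell to 30.2% of the vector level. MT1G itself went from 0 reads to 150 ± 25.9 normalized read counts, at least 148-fold higher against the floor of 3 reads over the 3 vector libraries. Of 13914 genes tested with limma, 1604 were higher and 1575 lower at an adjusted p threshold of 0.05.

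This comparison asked what MT1G overexpression does to transcripts that the title places in the sorafenib response. It cannot separate MT1G itself from how the construct was delivered or from the interferon response. KLF4 stood at 429 ± 27 with MT1G and 58.3 ± 4.76 with vector (log2 change 2.86, SE 0.14, adjusted p = 3.68e-12). CA9 stood at 18.9 ± 7.36 and 62.9 ± 13.9 (log2 change -1.73, SE 0.29, adjusted p = 0.00027). DNMT1 stood at 6344 ± 176 and 7703 ± 100 (log2 change -0.28, SE 0.07, adjusted p = 0.00932). The DNMT1 call was lost without vector replicate 2 (adjusted p = 0.0618) or 3 (adjusted p = 0.0668), in a range from 0.000479 to 0.0668 over 12 alternatives, while its log2 change stayed between -0.30 and -0.27. The deposited comparison table of the authors gave log2 changes of -0.28 for DNMT1, 9.61 for MT1G, 2.89 for KLF4 and -1.69 for CA9.

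Among the largest rises were OAS2, OASL, IFI44, IFIT2 and IFIT1, all interferon-stimulated genes of the fixed list. Their log2 changes were 7.05, 6.16, 5.57, 5.29 and 4.89. The largest falls were smaller: -1.81 for the adhesion gene CADM4, -1.75 for the myosin kinase MYLK3, -1.73 for the Wnt inhibitor NOTUM, -1.53 for the troponin TNNC1, -1.32 for RIMS4 and -1.29 for WTIP.

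The interferon-stimulated list passed camera (adjusted p = 5.17e-24), and it was the only list of 26 that also passed with an estimated correlation (adjusted p = 0.00814). At an unadjusted p under 0.05 with that correlation there were 7 higher lists and 0 lower, while fry passed 16 lists and its mixed form 23. Members that did not pass included MX1 at 0.01, BST2 at -0.14 and IFI35 at -0.06 on the log2 scale, named after their values were seen. ERK output genes rose in 12 of 17 cases and none fell (median 0.467, camera adjusted p = 2.56e-08, and adjusted p = 0.104 with an estimated correlation), with the feedback inhibitors DUSP4 at 1.28 and SPRY2 at 1.77 and the factor ETV5 at 2.43. NF-kB inflammatory genes rose in 6 of 12 cases and none fell (median 0.395, camera adjusted p = 3.71e-05, and adjusted p = 0.104 with an estimated correlation), with the cytokine IL6 at 2.97 and TNFAIP3 at 1.58. Mesenchymal transition genes rose in 9 of 20 cases and fell in 3 (median 0.324, camera adjusted p = 0.000321, and adjusted p = 0.285 with an estimated correlation). The matrix gene FN1 rose from 553 ± 20.8 to 4431 ± 412, and TGFBI by 1.24 on the log2 scale, while TAGLN changed by -1.16.

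**Figure D3:**
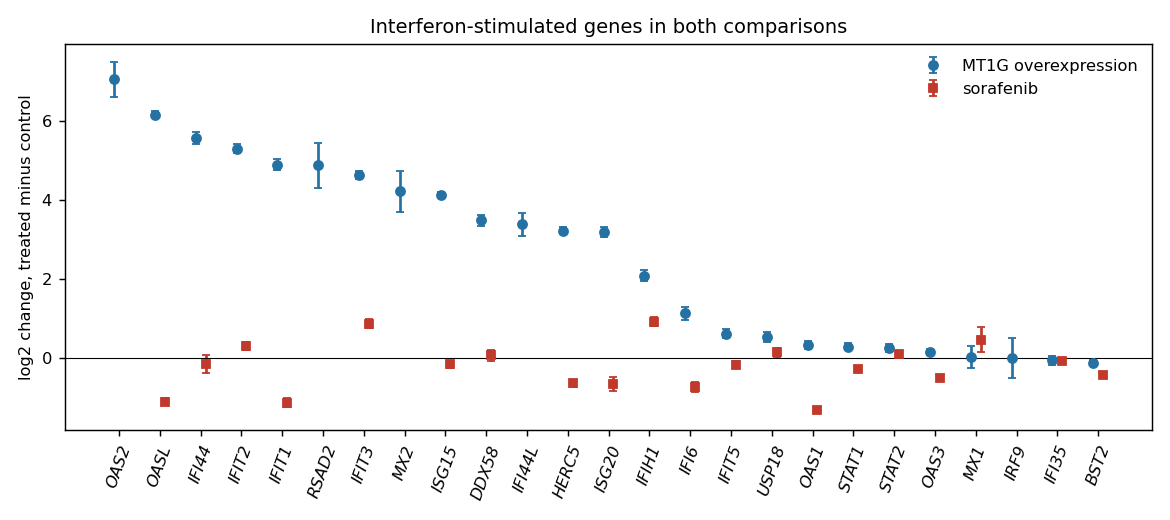
Log2 change with its SE (vertical axis) of each tested interferon-stimulated gene with MT1G overexpression (circles) and with sorafenib (squares). OAS2, OASL and IFI44 rose most with MT1G overexpression, while OASL and IFIT1 fell with sorafenib. Genes without a square had too few reads in the sorafenib experiment.

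Metallothioneins rose in 4 of 5 cases (median 0.691, camera adjusted p = 0.000321, and adjusted p = 0.104 with an estimated correlation), but 1 of these is MT1G itself, which the design raised. Without MT1G, 3 of 4 rose (median 0.643, camera adjusted p = 0.0119, and adjusted p = 0.176 with an estimated correlation), and how reads matching several of these near-identical genes were counted was not stated. MT2A rose by 0.60 and MT1X by 0.71. The MT2A call was lost without MT1G replicate 2 (adjusted p = 0.0687, from 2.55e-11 over the alternatives). The MT1X call was lost without vector replicate 2 (adjusted p = 0.0512) and in DESeq2 (adjusted p = 0.0586, from 0.0154 over the alternatives). Metal transport genes rose in 6 of 14 cases and none fell (median 0.258, camera adjusted p = 0.000483, and adjusted p = 0.176 with an estimated correlation), with the zinc exporter SLC30A1 at 0.42 and the importer SLC39A8 at 0.43. Unfolded protein genes rose in 6 of 21 cases and fell in 1 (median 0.158, camera adjusted p = 0.000321, and adjusted p = 0.176 with an estimated correlation), with the chaperone HSP90B1 at 0.59. KLF and SP factors rose in 8 of 17 cases and none fell (median 0.231, camera adjusted p = 0.00189, and adjusted p = 0.114 with an estimated correlation), with SP3 at 0.44 and KLF12 at 0.82.

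The 5 lists that were lower changed little per gene. Glycolysis genes fell in 9 of 19 cases (median -0.222, camera adjusted p = 0.000321, and adjusted p = 0.385 with an estimated correlation), with ALDOA at -0.80 and ENO2 at -0.68. S phase genes fell in 9 of 35 cases (median -0.175, camera adjusted p = 0.000983, and adjusted p = 0.385 with an estimated correlation), with TYMS at -0.39. Respiratory chain genes fell in 6 of 35 cases and rose in 1 (median -0.111, camera adjusted p = 0.0112, and adjusted p = 0.387 with an estimated correlation), and the call for ATP5F1B at -0.29 was lost without vector replicate 2 (adjusted p = 0.0991, from 0.000717 over the alternatives) or 3 (adjusted p = 0.0821). Fatty acid synthesis genes fell in 7 of 14 cases (median -0.221, camera adjusted p = 0.0137, and adjusted p = 0.303 with an estimated correlation), with FASN at -0.35. That list was not called without MT1G replicate 3 (adjusted p = 0.0632, from 0.00289 over the leave-one-out fits). Sterol genes fell in 8 of 25 cases and rose in 1 (median -0.141, camera adjusted p = 0.0354, and adjusted p = 0.303 with an estimated correlation), with DHCR7 at -0.35, and that list was not called without MT1G replicate 2 (adjusted p = 0.0502, from 0.0246). The sterol and respiratory chain medians lay inside the range of matched random lists, from -0.169 to 0.0553 and from -0.164 to 0.0301.

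Of 20 p53 target genes 4 rose, including the cell cycle inhibitor CDKN1A at 1.87, and 1 fell (camera adjusted p = 0.151, and from 0.0375 without MT1G replicate 2 to 0.466 over the leave-one-out fits). Of 32 hypoxia-inducible genes 6 rose, with BHLHE40 at 0.45, and 6 fell, with ALDOA at -0.80 (camera adjusted p = 0.747). Of 20 ferroptosis genes 6 rose, led by the prostaglandin synthase PTGS2 at 2.39, and 5 fell, with LPCAT3 at -0.47 (camera adjusted p = 0.456). In both lists the median (0.0298 and -0.0572) and the mean (-0.0232 and 0.147) differed in sign. Of 32 ATF4 genes 6 rose and 7 fell, with PHGDH at -0.71 and SLC7A11 at 0.64 (camera adjusted p = 0.486). Of 25 NRF2 genes 4 rose, with ABCC3 at 0.76, and 9 fell, with PGD at -0.39 (camera adjusted p = 0.13). Of 34 G2 and mitosis genes 5 rose and 10 fell, with AURKB at -0.41 and BUB1 at 0.32 (camera adjusted p = 0.486). DNA methylation genes gave 2 up and 4 down of 13, with IDH2 at -0.66 and IDH1 at 0.32 (camera adjusted p = 0.386). Of the 8 hepatocyte genes with enough reads 3 were down, with HNF4A at -0.59 (camera adjusted p = 0.0578, and from 0.0312 without vector replicate 2 to 0.0829). Heat shock genes gave 3 up and 1 down of 14 (camera adjusted p = 0.609), histone genes 2 up of 12 (camera adjusted p = 0.0578, and from 0.0198 without vector replicate 3 to 0.153) and mitochondrially encoded genes 1 up and 1 down of 13 (camera adjusted p = 0.445). Carbonic anhydrases gave 1 up and 1 down of 6 (camera adjusted p = 0.747) and stellate cell markers 2 up of 6, with LUM at 0.46 (camera adjusted p = 0.18). Acute phase, leukocyte and endothelial lists had 3, 1 and 1 tested members. Adjusted over the list alone, the counts up and down became 5 and 0 for metallothioneins, 8 and 0 for metal transport, 14 and 0 for ERK output, 20 and 0 for interferon-stimulated, 7 and 0 for NF-kB, 11 and 3 for mesenchymal transition, 0 and 12 for S phase and 0 and 10 for glycolysis genes. They became 0 and 8 for fatty acid synthesis, 0 and 6 for respiratory chain, 3 and 6 for DNA methylation, 7 and 6 for hypoxia-inducible, 6 and 10 for G2 and mitosis, 1 and 2 for acute phase, 0 and 1 for endothelial and 1 and 0 for histone genes.

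Over all genes tested with MT1G overexpression, 5486 of 13914 had groups that did not overlap, where chance gives 10%. The 10% of genes with the highest mean had a median log2 change of -0.131 and the 10% with the lowest mean 0.066, and the mitochondrial share was 4.72 ± 0.31% with MT1G and 4.23 ± 0.35% with vector. Without vector replicate 2 the counts of called genes were 1062 higher and 824 lower, and without vector replicate 3 they were 1007 and 764.

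KLF4, PTGS2 and TNFAIP3 were among the genes that rose in both experiments, and CA9, the liver transcription factor CEBPA and MYLK3 were among those that fell in both. Of 13748 genes tested in both, 552 were higher in both and 869 lower in both, where independence gave 490 and 610 (odds ratios 1.22 and 2.13, Fisher's exact test p = 0.00037 and 1.48e-44). With a mean of at least 100 in both, the odds ratios were 1.34 and 1.67. Lower calls numbered 163 (sorafenib) and 23 (MT1G) in the 10% of genes with the lowest mean, and 1008 and 390 in the highest 10%. This shared trend can by itself give an excess of shared falls, and its part was not tested. CEBPA changed by -1.65 with sorafenib and -0.99 with MT1G, PTGS2 by 2.24 and 2.39, and TNFAIP3 by 4.59 and 1.58 on the log2 scale. Genes called in opposite directions numbered 298 (higher with sorafenib and lower with MT1G, where independence gave 491) and 610 (the reverse, where it gave 608). OASL was lower with sorafenib (-1.11) and higher with MT1G (6.16), as was IFIT1 (-1.14 and 4.89). Across genes the correlation of log2 changes was 0.155 (Pearson) and 0.15 (Spearman), and genes are not independent replicates. With an absolute log2 change of at least 1 in both, 68 genes were higher and 17 lower in both, where independence gave 25.3 and 5. At that size 28 genes were lower with sorafenib and higher with MT1G, where independence gave 18.7 (odds ratio 1.58, Fisher's exact test p = 0.0285). Among 10137 genes with a mean of at least 100 in both, 541 went that way, where independence gave 590 (odds ratio 0.839, Fisher's exact test p = 0.00372), so the direction of this departure changed with the setting.

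**Figure D4:**
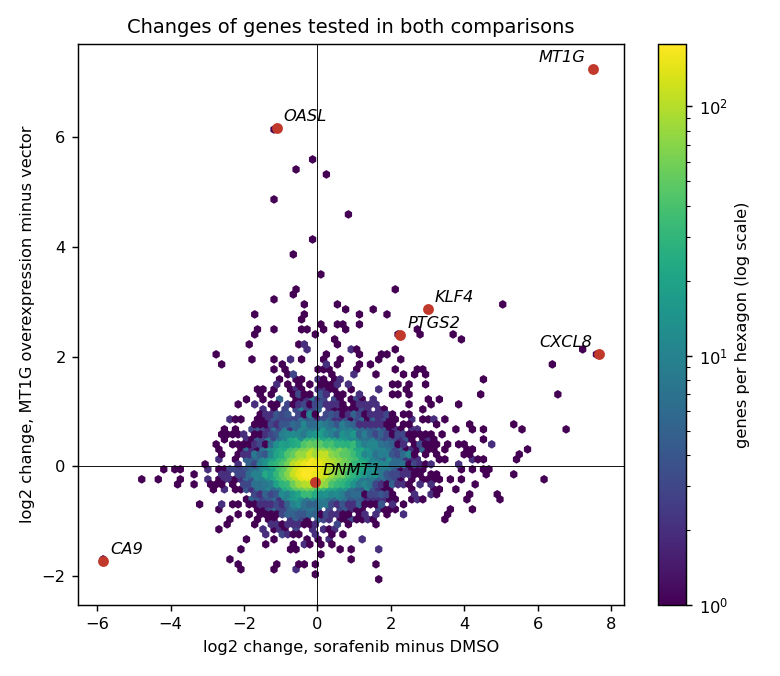
Log2 change with sorafenib (horizontal axis) against log2 change with MT1G overexpression (vertical axis) for 13748 genes, coloured by genes per hexagon on a log scale. KLF4, MT1G, CXCL8 and PTGS2 lay high on both axes, CA9 low on both, and OASL was high with MT1G overexpression alone.

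Open chromatin differed between sorafenib and DMSO at many places, but the title genes had few gained or lost regions. Within 2 kb of its span KLF4 had 3 open regions, each of them in all 4 libraries. The region from 107489407 to 107490515 had enrichments of 11.7 and 10.6 with sorafenib and 6.86 and 8.71 with DMSO. From 107484200 to 107484434 they went the other way (5.66 and 4.32 against 7.45 and 5.8), and from 107488422 to 107489257 the groups overlapped. These differences were not tested. MT1G had 1 weak region, in sorafenib replicate 4 alone (chromosome 16, 56668486 to 56668660, enrichment 2.65). DNMT1 had a region of 1642 bp at the upper end of its span open in all 4 libraries (chromosome 19, 10193783 to 10195424) and 1 gained region inside the gene (10150223 to 10150475, enrichments 2.94 and 3.87). Within 2 kb of CA9 lay 3 regions, none of them in all 4 libraries. Of 220925 merged regions 14133 (6.40%) were open in both sorafenib libraries and in neither DMSO library, 26467 (12%) showed the reverse, and 75611 were open in all 4.

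This comparison asked where accessibility changes with sorafenib. The strongest gained regions lay on chromosome 3 (163481637 to 163482117, nearest gene RNU7-82P at 11371 bp), chromosome 7 (94022421 to 94023064, inside LOC130890646) and chromosome 11 (85495847 to 85496673, inside DLG2, a synaptic scaffold gene). Their enrichments over local background in the sorafenib libraries were 22.6 and 24.2, 21 and 20.2, and 21.8 and 20. The strongest lost regions lay on chromosome 12 (85765319 to 85766020), chromosome 13 (69439720 to 69440539) and chromosome 8 (53343894 to 53344776), each over 10 kb from the nearest listed gene, with DMSO enrichments from 19 to 22.9. Most were weaker: the smaller of the 2 enrichments had a median of 4.12 over gained and 4.61 over lost regions. In regions open in all 4 libraries that median was 7.43 with sorafenib and 9.24 with DMSO. Of the 13541 tested genes with a known place, 17.7% had a gained region within 2 kb and 32.8% a lost one. Among lists higher in RNA, genes with a gained and with a lost region numbered 6 and 1 of 18 for NF-kB, 8 and 4 of 23 for KLF and SP, 8 and 7 of 34 for ATF4, 3 and 9 of 20 for ERK output, 3 and 5 of 20 for p53, 1 and 0 of 21 for histone and 1 and 0 of 11 for metallothionein genes. Among lists lower in RNA they numbered 7 and 8 of 25 for sterol, 3 and 7 of 15 for fatty acid, 5 and 11 of 26 for NRF2, 5 and 10 of 32 for hypoxia-inducible, 2 and 4 of 21 for glycolysis, 3 and 6 of 35 for respiratory chain and 3 and 10 of 34 for hepatocyte genes. These shares were not tested. Libraries of the same group shared 0.690 (DMSO) and 0.611 (sorafenib) of their covered bases by the Jaccard index, and libraries of different groups 0.451 to 0.463.

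**Figure D5:**
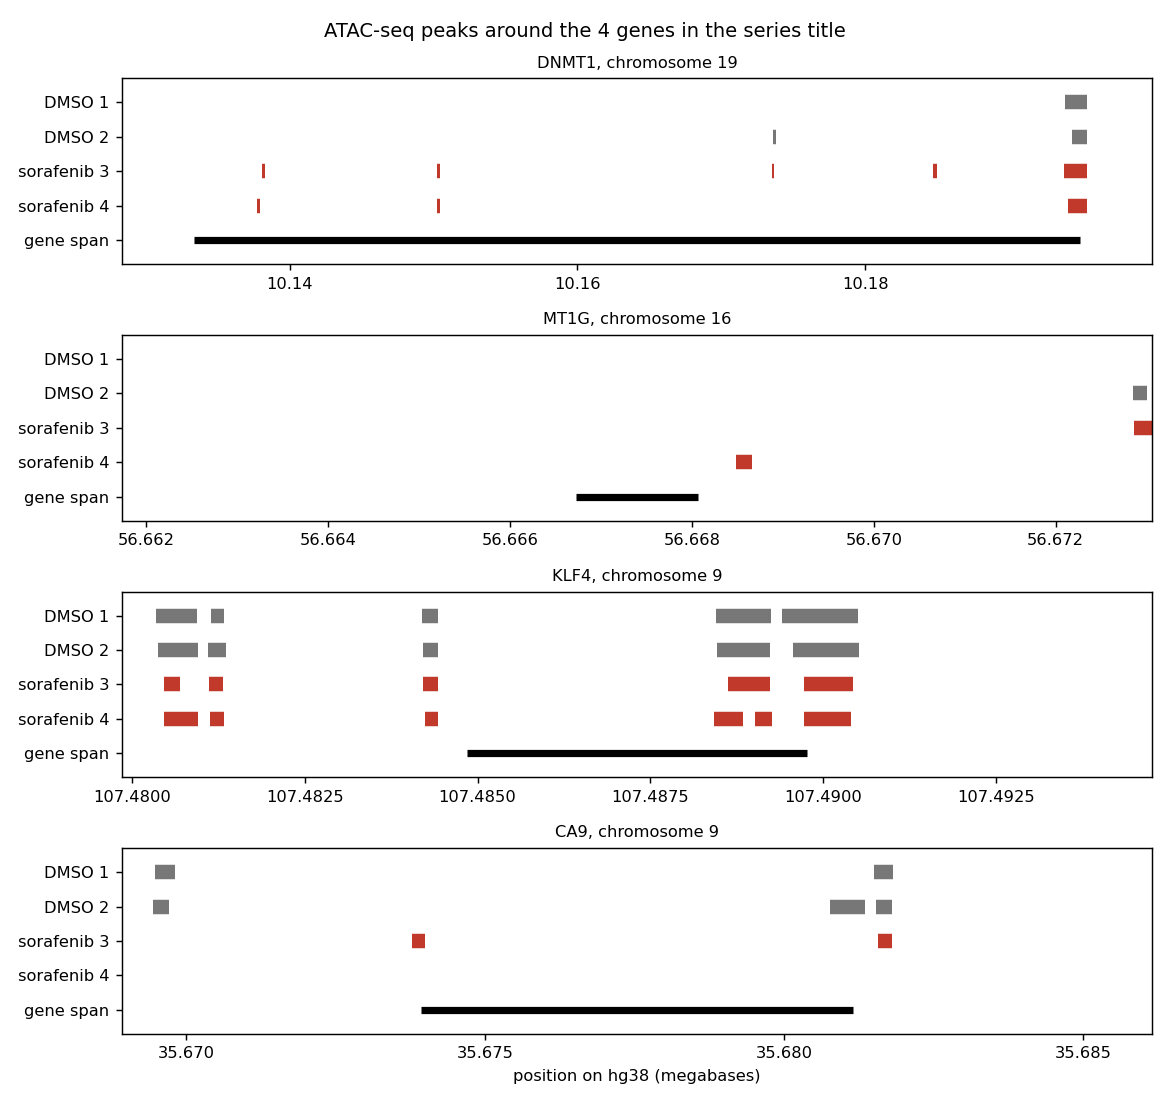
Called ATAC-seq peaks of the 4 libraries (rows) around DNMT1, MT1G, KLF4 and CA9, by position on hg38 in megabases (horizontal axis), with the gene span in black. KLF4 had peaks in all 4 libraries, and within 2 kb of MT1G the 1 peak was in sorafenib replicate 4, with stronger peaks in DMSO replicate 2 and sorafenib replicate 3 farther away.

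The libraries held 131239 and 156760 (DMSO) and 139294 and 135671 (sorafenib) peaks, with median widths of 449, 384, 285 and 280 bp. In the same order the median enrichment of a peak was 6.61, 6.95, 5.51 and 5.56, the median -log10 q 17.3, 25.4, 12 and 12.1, and the length covered 71.9, 76.9, 54.5 and 52.3 Mb, so both sorafenib libraries had weaker and narrower peaks. No test here separates the excess of lost regions from this lower signal, and the read depth behind them is not in the files. With 2 libraries against 2 the smallest exact two-sided p is 0.333, so no p-value was given, and leaving out 1 library loosened the need for both libraries of its group by construction. Gained and lost regions numbered 33486 and 33578 without sorafenib replicate 3, 36910 and 32676 without sorafenib replicate 4, 15421 and 52394 without DMSO replicate 1, and 20826 and 37810 without DMSO replicate 2.

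Genes near lost or gained regions had median expression changes close to those of other genes. The 3227 tested genes with a lost and no gained region within 2 kb of their span had a median log2 change of -0.0863 with sorafenib. The 1182 genes with a gained and no lost region had -0.0291, and 7260 genes with neither and a region in all 4 libraries -0.0257. Genes with a lost region had a median span of 61690 bp against 17826 bp for that last group. Within 10 classes of span length the remaining difference was -0.0231 for lost regions (two-sided permutation p = 0.11) and 0.0061 for gained regions (permutation p = 0.76). With windows of 10 kb the difference for lost regions was -0.0353 and passed (permutation p = 0.02, in a range from 0.00028 to 0.37 over the alternatives).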

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

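The test of MT1G transcript alone as the source of the interferon response was chosen only after the result was seen, and the test of interferon transcripts was written before it.

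Genes too scarce for the comparisons still separated the groups. With sorafenib, 234 genes under the mean of 10 normalized read counts stood at 0 in all 3 DMSO libraries and above the floor of 3 reads in each sorafenib library, against 5 genes in the reverse direction. Of the 234, 125 had a place in the gene table, 83 of them protein-coding and 20 long noncoding, and 102 carried only a clone name. The number of genes above 0 was 25173 ± 634 with sorafenib and 21644 ± 485 with DMSO (SD, n = 3). With MT1G overexpression there were 9 such genes, against 1 in the reverse direction, and the number of genes above 0 was 21241 ± 857 with MT1G and 20601 ± 337 with vector.

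The interferon gene IFNL1, singled out after its values were seen, also appeared with MT1G overexpression below the mean of 10. It stood at 7.99 ± 0.986 normalized read counts with MT1G (26 reads over 3 libraries) and at 0 with vector, at least 7.74-fold higher against the floor of 3 reads over the group. With sorafenib IFNL1 had 10 reads, and 0 with DMSO. IFNB1, also chosen after its values were seen, had 9 reads with MT1G and 0 with vector.

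Interferon-stimulated genes such as OAS2, OASL and IFIT1 rose with MT1G overexpression. In the sorafenib experiment, where MT1G transcript reached a similar level, the median log2 change of the same list was -0.173 (95% bootstrap interval from -0.522 to 0.103), so the list did not rise there. Sorafenib changed 70.3% of tested genes and could have held such genes down, and MT1G protein was not measured. These libraries therefore cannot decide whether a rise in MT1G transcript is enough by itself. Of 22 interferon genes, 0 reached a mean of 10 with MT1G overexpression, but IFNL1 was present below that level and interferons may act at low or passing levels, so the limit written beforehand was too strict. Whether interferon transcripts made by the cells stood behind the response cannot be told apart from other sources with these libraries. An effect of the MT1G protein itself, or of how the construct was delivered, stays open and was not tested.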

How the results depend on the processing

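The alternatives with edgeR, with gene span windows, with matched random lists and with metallothioneins without MT1G were chosen only after the results were seen, and all others were set before the data were examined.

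Counts of changed genes with sorafenib stayed within 1.5 times the reported counts under TMM factors, no filter on low values, pseudocounts of 0.5 and 5, DESeq2, edgeR and the omission of any library, from 4607 to 7034 higher and from 4951 to 5496 lower. Requiring an absolute log2 change of at least 1 left 2175 higher and 1024 lower, and 289 and 69 with MT1G overexpression, since by construction it removes smaller changes. It likewise left 68 genes higher and 17 lower in both comparisons. With MT1G overexpression, leaving out each library gave 1007 to 1818 higher and 764 to 2013 lower genes. The counts were 1062 and 824 without vector replicate 2, and 1007 and 764 without vector replicate 3, and the cause was not tested. DESeq2 gave 1418 and 1473 and edgeR 1684 and 1455.

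Most named genes were picked for a small p or a large change in these same libraries, so their calls say little on other called genes. Of all 10484 genes called with sorafenib, 9468 (without sorafenib replicate 2) to 10031 (without DMSO replicate 3) were also called with 1 library left out. With MT1G overexpression these were 1734 (without vector replicate 3) to 2875 (without MT1G replicate 3) of 3179. Of 88 named genes called with sorafenib, all stayed past the threshold in the same direction under 12 alternatives each, with CA9 from -6.46 (without sorafenib replicate 2) to -4.88 on the log2 scale. Of 78 called with MT1G overexpression, 13 lost their call under at least 1 alternative and none reversed, in 20 of 21 cases when a library was left out. These were, among others, DNMT1 (adjusted p = 0.0618 without vector replicate 2 and 0.0668 without vector replicate 3, from 0.000479), ATP5F1B (0.0991 and 0.0821, from 0.000717), MT1X (0.0512 without vector replicate 2 and 0.0586 in DESeq2, from 0.0154), MT2A (0.0687 without MT1G replicate 2, from 2.55e-11), HSPH1 (adjusted p = 0.113 without MT1G replicate 2, 0.115 without vector replicate 2 and 0.13 without vector replicate 3, from 0.00856) and HSP90AA1 (0.155, 0.105 and 0.145, from 0.00066).

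With an estimated correlation, camera called 0 lists higher and 0 lower with sorafenib (4 and 4 at an unadjusted p under 0.05, and 24 lists by fry), and 1 higher and 0 lower with MT1G overexpression (7 and 0 unadjusted, and 16 by fry). Fry does not compare a list with the other genes, so its counts answer a different question. The estimated correlation leaves few degrees of freedom with 6 libraries, and what part of the loss came from this was not tested. Leaving out a library gave 7 higher lists and 8 to 9 lower with sorafenib, and 8 to 9 higher and 4 to 6 lower with MT1G overexpression. Fatty acid synthesis genes were not called without MT1G replicate 3 (adjusted p = 0.0632, from 0.00289) and sterol genes without MT1G replicate 2 (0.0502, from 0.0246). Carbonic anhydrases became lower with sorafenib without sorafenib replicate 2 (0.0465, up to 0.0758). With MT1G overexpression, hepatocyte genes became lower without vector replicate 2 (0.0312, up to 0.0829), p53 targets higher without MT1G replicate 2 (0.0375, up to 0.466) and histones higher without vector replicate 3 (0.0198, up to 0.153). Among lower lists with MT1G overexpression 3 of 5 also lay outside matched random lists, since that comparison takes out the trend with mean expression.

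The replicate numbers did not pair the samples: libraries with the same number correlated at -0.027, 0.029 and -0.056 (sorafenib) and -0.14, 0.043 and -0.063 (MT1G overexpression) after group means were removed. With a replicate block, 4992 genes were higher and 5201 lower with sorafenib and 1691 and 1566 with MT1G overexpression, and 7 and 9 lists and 8 and 6 lists. The added lower lists were carbonic anhydrases with sorafenib (adjusted p = 0.0437) and hepatocyte genes with MT1G overexpression (adjusted p = 0.0443).

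Leaving out 1 ATAC-seq library gave 15421 to 36910 gained and 32676 to 52394 lost regions. By construction this needs a peak, or none, in 1 library of a group in place of both: 33486 gained and 33578 lost without sorafenib replicate 3, 36910 and 32676 without sorafenib replicate 4, 15421 and 52394 without DMSO replicate 1, and 20826 and 37810 without DMSO replicate 2. Since the loosening favours gained regions when a sorafenib library is left out and lost regions when a DMSO library is, these counts say nothing on the balance of both. Other peak choices gave 9439 to 14827 gained and 22968 to 26297 lost. The expression difference of genes with a lost region was -0.0606 without length classes (permutation p = 0.00028), where longer genes hold more regions, and -0.0353 with a 10 kb window (permutation p = 0.02), whose cause was not tested, and over the alternatives p ran from 0.00028 to 0.37. The planned windows at transcription starts were not run because the gene table gave no strand. ATAC-seq read depth is unknown, so what depth limits in the peak lists could not be measured.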

Other observations

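The tests of low depth, of S phase and of the added gene lists were chosen only after the results were seen.

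Splitting the 6 libraries of an RNA experiment into groups of 3 gives 10 splits, too few for a share under 0.05. With limma the real sorafenib split gave 10484 genes and the highest other split 0 (10794 and 90 at an unadjusted p under 0.05), and 1 of the 10 splits was as large. The real MT1G split gave 3179 genes and the highest other split 1 (4959 and 894 unadjusted), and 1 of the 10 splits was as large. For ATAC-seq the other splits of 4 libraries gave 851 and 2850, and 3514 and 775, regions open in one pair only.

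Most hepatocyte genes were nearly silent in these cells labelled Huh7. Of 34 listed genes, 24 stayed under 10 normalized read counts in all 12 libraries and 5 were at 0 in all, among them ALB and APOB, chosen after their values were seen. Low sequencing depth would have removed other genes too, and the library with the fewest still had 13708 genes at 10 or more, which argues against it for these 24. Of the 24 silent genes 16 had an open region within 2 kb in both DMSO ATAC-seq libraries, where matched random genes had a median of 19 and a 5th percentile of 16, so whether these genes are also closed cannot be told apart at this number of genes, and the limit for that verdict was widened after the value was seen. AFP reached at most 4.97 and SERPINA1 at most 1.07 in any of the 12 libraries, also chosen after their values were seen. Together with the keratin and surface genes abundant with DMSO, given below, these values leave open whether the label Huh7 holds. That question touches every result here, and no test of cell line identity was run. A difference between cell stocks may explain the 24 silent genes but was not tested.

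Replication-dependent histone transcripts such as H2AC6 and H3C10 rose with sorafenib. The median log2 change of S phase genes was 0.0311 (95% bootstrap interval from -0.133 to 0.17), under the 0.5 set for more cells in S phase, which argues against it as the whole cause, although the median lay above the range of random lists matched on mean expression (from -0.409 to -0.0269). In an added list of RNAs without a poly(A) tail the 4 members with enough reads had a median of -0.543 with an interval from -1.26 to 2.25, which holds the bound of 2.07 set from the histone median, so weaker selection of polyadenylated RNA cannot be told apart with 4 RNAs. Mitochondrial transfer RNAs, which normally lack the tail, went down, but whether their reads came from transfer RNAs without the tail is unknown. The U1 variant RNVU1-34 went up by 7.24 on the log2 scale, but it is listed as a pseudogene, and whether its reads came from an RNA without the tail is unknown. A change in histone RNA ends or stability caused by sorafenib stays open and was not tested.

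Some keratin, surface and cell cycle genes were abundant with DMSO, all chosen after their values were seen: KRT7 at 16570, KRT17 at 4778, ALPP at 5980, MSLN at 5274 and CDKN2A at 7272 normalized read counts. A list of keratin and surface genes had 9 of 10 lower with sorafenib (median -0.467, camera adjusted p = 0.00638, and adjusted p = 0.395 with an estimated correlation), inside the range of matched random lists from -0.562 to 0.014. With MT1G overexpression 3 were higher and 6 lower (median -0.352, camera adjusted p = 0.0822), outside the matched range from -0.247 to 0.049, and KRT17 rose by 1.38 and ALPP fell by 1.23.

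Mitochondrial transfer RNAs were lower with sorafenib in 8 of 8 cases (median -2.88), but 4 of the 8 had prompted the list, so no set test is given, and 1 of 8 was lower with MT1G overexpression. Cytosolic ribosomal protein genes were lower in 48 of 48 cases with sorafenib (median -0.466, camera adjusted p = 6.43e-10, and adjusted p = 0.395 with an estimated correlation), inside the matched random range from -0.483 to -0.297, and in 11 of 49 with MT1G overexpression (camera adjusted p = 2.69e-06, and adjusted p = 0.452 with an estimated correlation), where the median of -0.181 was inside the matched range from -0.203 to -0.103. Mitochondrial ribosomal genes had 5 higher and 27 lower of 50 (camera adjusted p = 0.00743, and adjusted p = 0.445 with an estimated correlation), with a median of -0.232 inside the matched range from -0.303 to 0.0444, and 5 lower of 50 with MT1G overexpression (camera adjusted p = 0.0679). Proteasome genes had 18 lower of 30 (camera adjusted p = 0.00638, and adjusted p = 0.395 with an estimated correlation), with a median of -0.205 inside the matched range from -0.443 to -0.083, and 1 higher and 1 lower of 30 with MT1G overexpression (camera adjusted p = 0.783). Peroxisome and fatty acid oxidation genes had 4 higher and 18 lower of 30 (camera adjusted p = 0.00646, and adjusted p = 0.232 with an estimated correlation) and, with MT1G overexpression, 2 higher and 7 lower of 30 (camera adjusted p = 0.0679). Their medians of -0.342 and -0.142 lay outside the matched ranges, from -0.312 to 0.184 and from -0.11 to 0.126.

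Sensors and factors of the interferon pathway, some of them also in the interferon-stimulated list, had 7 of 20 higher with MT1G overexpression (median 0.161, outside the matched range from -0.151 to 0.15, camera adjusted p = 0.00162, and adjusted p = 0.201 with an estimated correlation), with the RNA sensors DDX58 at 3.48 and IFIH1 at 2.08 on the log2 scale and the DNA sensor AIM2 at 2.23, chosen after their values were seen. Since this list was written after the interferon-stimulated result and shares DDX58 and IFIH1 with that list, its test and matched range partly restate that result. With sorafenib 4 were higher and 8 lower of 20 (median -0.258, inside the matched range from -0.381 to 0.27, camera adjusted p = 0.438).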
